A study of Mus musculus with 18 samples.

How the data were processed

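Expression was measured on 18 Affymetrix mouse arrays, 1 per sample. The samples were OCK reprogramming cultures of wild-type (wt) and Tcf3 knockout (ko) cells on 5 days, 5 iPSC clones, and 3 arrays of a partial iPSC clone treated with siRNA. Groups, clone numbers and days came from the sample labels, and every sample had a group. The deposited value table held 1 value per probe set and array, on a log2 scale, made by the authors with RMA (background correction, normalization across arrays and summary of probes), per the submitters' processing notes; the version and settings of RMA are not given in the sources used here. Every column of the deposited log2 values had the same lowest value, 5.64, which is the log2 of 50. Between 44.9% and 46.6% of the values on each array were equal to it, so levels below 50 had been set to a floor, a step that is seen in the values and that no label names. A value at the floor is only an upper limit.

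The table held 40508 probe sets, of which 13505 (33.3%) were at the floor on all 18 arrays. Gene names came from the annotation of the array platform: 31076 probe sets had 1 gene symbol, 636 had several and 8796 were not listed there and are unnamed here. Entrez identifiers of 30878 probe sets were found in a mouse reference gene table (assembly GRCm38.p6), and 0 symbols changed. That table was used for names, chromosomes and the order of genes only, since the sources used here name no genome build for the probes and no coordinates are printed. Probe sets of a single gene gave 17903 genes, 7906 of them with more than 1 probe set. The probe set with the highest mean over the 18 arrays stood for its gene, and the mean of a gene's probe sets was an alternative. After the floor, array medians lay between 5.85 and 5.94, the upper quartiles between 7.99 and 8.18, and the number of genes above the floor between 12102 and 12499. No probe set was a control probe set by its name. The number of arrays limits the precision of every value.

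Comparisons, tests, gene lists and the rule for naming genes were fixed before the data were examined. All tests used limma 3.58.1 in R 4.3.3 on the log2 values with Benjamini-Hochberg adjustment and a threshold of 0.05. The culture effect of Tcf3 loss was the ko coefficient in a fit of the 10 culture arrays with day as a block, so the days stand in for replicates. The change per day was the mean of the wt and ko straight-line slopes over days 11 to 26, and the difference of those slopes was tested in the same fit. That fit takes the 10 arrays as independent although wt and ko arrays share each sampling day. The comparisons between clones used 1 fit of 8 arrays with a mean per group. In it the lone OSK wt and control siRNA arrays are assumed to vary like the groups with 2 arrays, which leaves 3 residual degrees of freedom. A negative or positive value always means the group named first minus the group named after it.

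The variance model departs from the plan, and this was decided after the floor had been seen. The plan was limma's plain moderated test over all genes. Genes at the floor have residual variances at or near 0, and over all 17903 genes they pulled the prior standard deviation down to 0.0046 in the culture fit with day as a block and 0.0044 in the clone fit, with 0.38 and 0.39 prior degrees of freedom. Of the calls it then made, 43 of 123 (OSK ko against wt) and 97 of 252 (Tcf3 siRNA) were genes with no residual spread at all. In the results reported here the prior was instead estimated from genes above the floor on every array of the fit (prior standard deviations 0.118, 0.183 and 0.112 for the 3 fits), a gene with a floored array was given at least the prior variance, and genes at the floor on every array of the compared groups were not tested. The counts from the plan as written are given beside each result. Where a group lay at the floor on all its arrays, the fold is given as "at least", computed from the mean of the brighter group and the floor.

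The same code was tested on simulated data with 200 changed genes in 10 simulations per comparison, with changes of log2 1 and 2. It found 88.3% and 91.8% of them for the culture effect of Tcf3 loss, 49.5% and 87.9% for a change over the 15 days of the time course, 0.9% and 31.4% for a slope difference of that total size, 56.8% and 85.9% for OSK ko against wt, 74.2% and 89.3% for OCK against OSK, and 55.2% and 84.0% for the siRNA. Between 4.51% and 5.83% of its calls were false. The simulated errors were independent between genes and arrays and were drawn from the prior of the same fit, so this share checks the code only. They held no deviation shared by a day and no unequal spread between groups. The share of false calls in the real data is therefore not known from them.

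Gene lists, 21 in all, covered the pluripotency network, Tcf3-repressed ES cell genes, Wnt/beta-catenin targets, Tcf/Lef and Wnt components, mesenchymal, epithelial, mesoderm, endoderm, neural and epiblast, trophoblast, germline, two-cell-like, cell cycle, p53 and senescence, interferon response, macrophage and blood, endothelial, muscle, imprinted, glycolysis and sex-linked genes. The lists came from general knowledge of the field and were not chosen on these samples. Some lists share genes, so their calls are not independent. Nanog, Esrrb, Tfcp2l1, Klf2, Tbx3, Nr0b1, Nr5a2 and Tcl1 are in both the pluripotency and the Tcf3-repressed list. Cdx1 and Sp5 are in both the Tcf3-repressed and the Wnt target list, and Tcf7 and Lef1 in both the Wnt target and the Tcf/Lef list. A list was tested where at least 3 of its genes were, with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the lists of a comparison. Members were counted by the test over all genes and again adjusted over the list alone. The genes named for each comparison are Tcf7l1, the 10 largest rises and 10 largest falls among genes that passed and moved the same way on every day, clone or siRNA (filled up with the largest changes that did not pass, said to be so), and up to 4 members of each list, those with the 2 largest rises and 2 largest falls; genes without a proper name were passed over.

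Alternatives covered the mean of probe sets, a filter at log2 6, quantile normalization, centring of each array on its median, a variance trend, each day, clone or siRNA left out, other sets of arrays in the fit, other day terms and the clone number as a block. Alternatives added after the data were examined were limma's plain prior, only genes above the floor on every array, the plan as written, only days 19, 22 and 26, a fit without chromosomes X, Y and 12, crossed clone numbers, a line through the 5 day means for the change per day and day as a block for the slope difference. Sign-flip tests over days and the other correlations used R, and the tables of genes, the correlations of array pairs and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.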

Results

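Gene expression was measured on 18 arrays of mouse cells at several points of reprogramming to induced pluripotent stem cells (iPSC), with and without Tcf3. Tcf3 is the former name of Tcf7l1, a DNA-binding partner of beta-catenin that represses its targets in ES cells. OCK stands for the factors Oct4, c-Myc and Klf4, and OSK for Oct4, Sox2 and Klf4. OCK cultures of wild-type (wt) and Tcf3 knockout (ko) cells were sampled on days 11, 15, 19, 22 and 26, with 1 array per genotype and day. The established clones were 1 OSK wt, 2 OSK ko and 2 OCK ko iPSC clones. A partial OCK iPSC clone was treated with a control siRNA (1 array) or with 1 of 2 independent siRNAs against Tcf3 (A and B, 1 array each) and collected on day 2. Values are log2 RMA signal, and values at the floor of 5.64 stand for any lower level. The labels do not say that clones or siRNA arrays came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Nor do they say whether the days of a genotype were sampled from 1 culture. A lasting difference between the wt and ko cultures therefore cannot be told from an effect of genotype. Between 12102 and 12499 of 17903 genes were above the floor on an array. Array pairs of a group correlated with r = 0.998 (OSK ko), r = 0.988 (OCK ko) and r = 0.996 (Tcf3 siRNAs). These correlations run across all 40508 probe sets, of which 33.3% were at the floor on every array. Neither probe sets nor genes are independent replicates.

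Tcf7l1 was lower in every Tcf3-depleted group that had a control, but stayed well above the floor. In the cultures its signal was 9.90, 9.70, 9.07, 9.06 and 9.17 in wt and 9.48, 9.37, 8.61, 8.10 and 8.44 in ko on days 11, 15, 19, 22 and 26. The OSK wt clone had 10.68, the OSK ko clones 9.49 and 9.37, and the OCK ko clones 9.45 and 9.56. The control siRNA array had 9.93, and the arrays of siRNAs A and B had 8.80 and 8.77. A second Tcf7l1 probe set, not used for the gene, had 9.86 with control siRNA and 7.79 and 7.56 with siRNAs A and B. In the OSK clones it had 10.07 in wt and 8.82 and 8.67 in ko. With the mean of both probe sets the difference after siRNA was -1.66. Tcf7l1 fell in OSK ko against wt clones (-1.25 ± 0.11, limma adjusted p = 0.0215) and after Tcf3 siRNA (-1.15 ± 0.11, adjusted p = 0.0495). In the cultures the ko minus wt difference was -0.58 ± 0.10 and lower on all 5 days, but did not pass over all genes (adjusted p = 1); adjusted over the list alone it passed. The OSK call was lost without OSK ko clone 1 (adjusted p = 0.154), without clone 2 (0.180) and in a fit of the 5 iPSC arrays (0.147). The siRNA call was lost without siRNA A (0.230) or B (0.294), with quantile normalization (0.0530), with median centring (0.0621) and among genes above the floor on every array (0.138). Where the probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside it would not check the knockout.

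**Figure D1:**
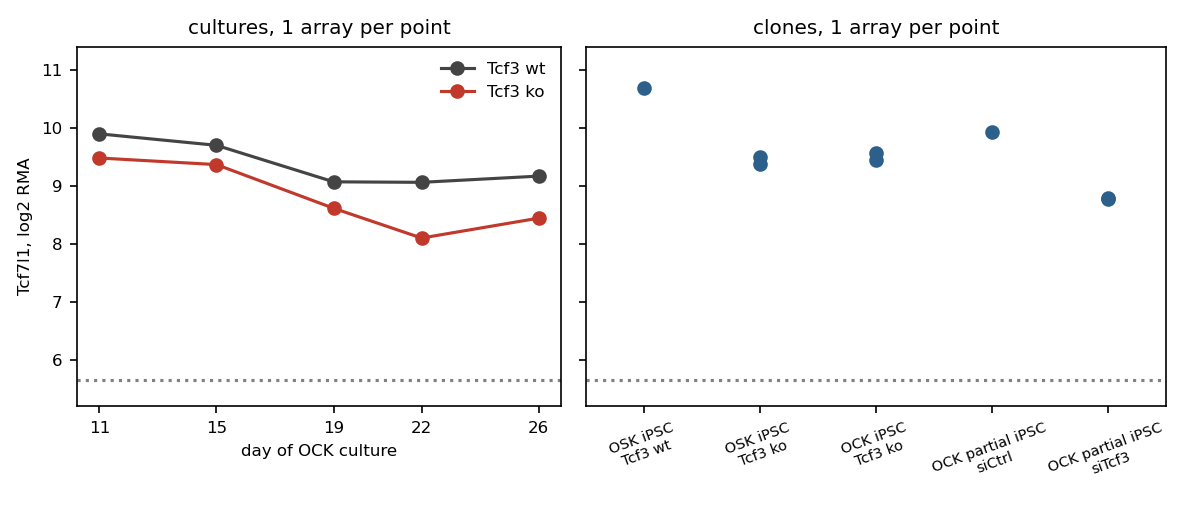
Tcf7l1 signal (log2 RMA) on each of the 18 arrays by group, with the floor of 5.64 marked. Each ko culture lies below the wt culture of its day, both OSK ko clones lie below the OSK wt clone (9.49 and 9.37 against 10.68), and both Tcf3 siRNA arrays lie below the control siRNA (8.80 and 8.77 against 9.93).

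The time course of both genotypes together asks what changed as OCK cultures moved from day 11 to day 26. Genes of the pluripotent state rose: Dppa5a by 0.39 ± 0.028 log2 per day (SE, 10 arrays; adjusted p = 0.00207), Sox2 by 0.34 ± 0.06 and Nanog, a core factor of that state, by 0.27 ± 0.037. Epcam and Cdh1, which encode epithelial adhesion proteins, rose by 0.23 ± 0.026 and 0.19 ± 0.032 per day. Interferon-induced genes fell, with -0.36 ± 0.079 for the chemokine Cxcl10, -0.33 ± 0.049 for Ifit1 and -0.32 ± 0.039 for Irf7. Of 13428 genes tested with limma, 4921 passed, of which 2411 rose and 2510 fell. Of these, 1113 rose and 950 fell at least 2-fold over the 15 days. This fit has no term for the deviations that both arrays of a day share, so its standard errors take the 10 arrays as independent. A line through the 5 day means, which does not, called 424 genes (256 higher, 168 lower), all among the 4921, with 4484 at an unadjusted p under 0.05. Of the genes named in this paragraph Sox2 (adjusted p = 0.0515), Cdh1 (0.0505), Slc38a5 (0.0541), Rhox5 (0.0553), Fabp7 (0.0550) and Sprr1b (0.0601) did not pass in it, nor did several of those named below, Tcf7l1 (0.0701) among them. The other largest rises among named genes were those of the amino acid transporter Slc38a5 (0.41 ± 0.073), Bex4 (0.32), Rhox5 (0.31), Fbxo15 (0.31), Fabp7 (0.31), Sox1 (0.31), Myb (0.30) and Klk1 (0.30). The other largest falls were those of Ifit3 (-0.32), Usp18 (-0.31), Oasl2 (-0.30) and Gbp3 (-0.28), all interferon-induced, and of the keratinocyte envelope genes Lce1b (-0.27) and Sprr1b (-0.26) and the corneal proteoglycan Kera (-0.27).

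Of 26 pluripotency genes tested, 18 rose, 0 fell and 8 did not pass, and 19 rose adjusted over the list alone. Camera placed the list above other genes (adjusted p = 5.07e-12; adjusted p = 0.0281 with an estimated correlation), the only list here whose call held with that correlation. Of 20 epithelial genes 15 rose, with Cdh1 among them (camera adjusted p = 4.64e-09; adjusted p = 0.226 with an estimated correlation). Of 31 mesenchymal genes 21 fell, 25 adjusted over the list alone, including the transcription factor Twist2 (-0.12) and the collagen gene Col5a1 (-0.12) (adjusted p = 5.2e-08; adjusted p = 0.329 with an estimated correlation). Of 18 cell cycle genes 17 rose, among them Bub1 (0.18) and Cenpa (0.17), which act at kinetochores and centromeres (adjusted p = 4.64e-09; adjusted p = 0.269 with an estimated correlation). Of 12 glycolysis genes 11 rose, among them Aldoc (0.24) and the glucose transporter Slc2a1 (0.20) (adjusted p = 2.71e-07; adjusted p = 0.145 with an estimated correlation). Of 17 interferon genes 16 fell, and all 17 fell adjusted over the list alone (adjusted p = 2.57e-14; adjusted p = 0.0984 with an estimated correlation). Of 14 macrophage and blood genes 9 fell, among them Lyz2 (-0.20) and the complement gene C1qb (-0.17) (adjusted p = 0.00231; adjusted p = 0.342 with an estimated correlation).

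Of 11 neural and epiblast genes 6 rose, 8 adjusted over the list alone, including Pax6 (0.20) (adjusted p = 0.000455; adjusted p = 0.0984 with an estimated correlation). Of 8 trophoblast genes 3 rose, including Krt7 (0.14) and Elf5 (0.14) (adjusted p = 0.0126; adjusted p = 0.112 with an estimated correlation). Of 10 Tcf3-repressed genes 5 rose, including Nanog and Nr0b1 (0.16) (adjusted p = 0.016; adjusted p = 0.329 with an estimated correlation). Of 14 imprinted genes 7 fell, 8 adjusted over the list alone with 1 that rose, including Cdkn1c (-0.099) and Plagl1 (-0.084) (adjusted p = 0.0348; adjusted p = 0.316 with an estimated correlation). No other list passed by camera, while fry, which tests whether a list's genes move one way without comparing them with other genes, called 15 of 20 lists: the 11 above and the mesoderm (0.014), endoderm (0.0351), germline (0.00584) and endothelial (0.0351) lists. With the day means camera called the same 11 lists, and the neural (0.000278), interferon (0.00503) and trophoblast (0.0185) calls then held with an estimated correlation, as the pluripotency call did (8.48e-06). Fry called 7 lists with the day means: pluripotency, Tcf3-repressed, neural, germline and interferon (0.0421 each), and trophoblast and glycolysis (0.045 each). Fewer members then passed over all genes: 9 pluripotency, 5 epithelial, 4 cell cycle, 3 glycolysis, 3 neural, 2 trophoblast and 2 Tcf3-repressed genes rose, 14 interferon and 1 imprinted fell, and 0 mesenchymal and 0 macrophage genes passed. Among endoderm genes 4 of 11 fell, with Gata6 at -0.089 and Dab2 at -0.084, and among p53 genes 1 rose (Pmaip1, 0.098) and 5 of 14 fell (Cdkn2b, -0.077). Among Wnt targets Myc (0.11) and Znrf3 (0.056) rose, and 0 of 11 passed adjusted over the list alone. Myc, like Pou5f1 (Oct4) and Klf4 in the pluripotency list, is a factor of the OCK set. Whether their probe sets also read introduced copies is not given in the sources used here. Of 15 Tcf/Lef components 3 fell, 2 adjusted over the list alone, with Tcf7l1 at -0.074 ± 0.016, and Tle1 (0.056) rose. In the mesoderm list Eomes (0.06) rose, in the germline list 2 of 4 rose with Tdrd12 at 0.047, and in the muscle list 3 of 8 rose with Mylpf at 0.17. In the endothelial list Cldn5 (0.16) rose and Tek (-0.029) fell, and 0 of 4 sex-linked genes passed. With the plan as written 3171 genes passed, 2943 of them shared, and median centring gave 35.5% rises among the calls against 49.0%. Leaving out day 11 gave 0 calls by limma (3954 at an unadjusted p under 0.05), leaving out day 15 gave 1935, and without day 26 the Tcf3-repressed (adjusted p = 0.329) and trophoblast (0.221) lists and without day 11 the imprinted list (0.191) did not pass.

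The similarity of each array to the OSK wt iPSC clone was measured as the correlation across 14228 genes. In wt cultures it was 0.723, 0.749, 0.790, 0.832 and 0.812 on the 5 days, and in ko cultures 0.715, 0.709, 0.803, 0.866 and 0.835. It was higher in ko than in wt on 3 of the 5 days (exact sign-flip permutation test over days, two-sided, p = 0.812, where 0.0625 is the smallest possible). The partial clone lay at 0.848 with control siRNA and at 0.861 and 0.864 with the Tcf3 siRNAs. The OSK ko clones both lay at 0.988 and the OCK ko clones at 0.969 and 0.978.

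**Figure D2:**
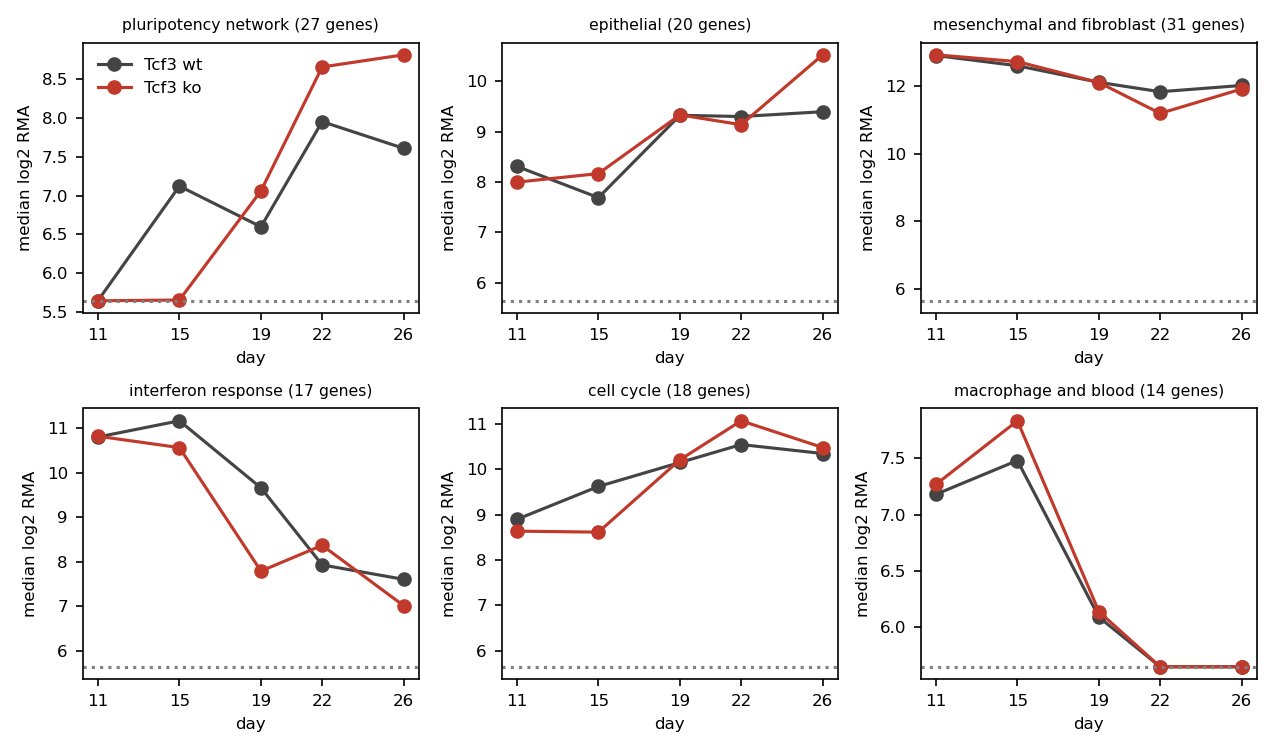
Median log2 RMA signal of 6 gene lists in the wt and ko cultures on each sampled day, with the floor dotted. The pluripotency, epithelial and cell cycle medians end higher than they began in both genotypes and the interferon medians end lower, and on day 26 the pluripotency median is 8.82 in ko and 7.61 in wt.

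The comparison of ko with wt cultures on matched days asks what the loss of Tcf3 did during OCK reprogramming. No gene passed limma's test over the 5 days. The fat cell hormone gene Adipoq (-1.01 ± 0.083, 5 arrays per genotype) and the heme carrier Hpx (-0.76 ± 0.066) came closest, both at adjusted p = 0.0674 and lower in ko on every day. The fatty acid transporter Cd36 was at -0.94 ± 0.17, the lipolysis inhibitor G0s2 at -0.66 ± 0.12 and the estrogen receptor Esr1 at -1.02 ± 0.38. Higher in ko, and not passing either, were the cytokine Il15 (0.43 ± 0.094), the fatty acid binding protein Fabp3 (0.56 ± 0.17) and the hormone gene Sct (0.56 ± 0.24). Of 13428 genes, 452 had an unadjusted p under 0.05 (264 higher, 188 lower), and the plain limma prior and the plan as written also called 0, with 472 and 598 genes at that level. Each of these counts is under a share of 0.05 of the genes tested, so none shows an excess of low p-values. Other named genes that did not pass were Slc40a1 (0.46), Elmo3 (0.44), Psma8 (0.43), Rassf6 (0.43), Ggps1 (0.41), Sbspon (0.40), Foxred2 (0.35), Prr15 (-0.85), Wfdc21 (-0.76), Nexmif (-0.68), Coch (-0.66) and Msi1 (-0.63).

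Several lists shifted as sets in ko cultures by camera at the preset correlation, and none of these calls held with an estimated correlation or by fry (smallest adjusted p = 0.749). Interferon genes lay lower (median -0.52, 16 of 17 negative, Cxcl10 -1.28 ± 0.85, Ifit1 -0.81 ± 0.49; adjusted p = 5.31e-06, and adjusted p = 0.43 with an estimated correlation). Mesenchymal genes were lower in 28 of 31 cases (median -0.097, Cdh2 -0.48; adjusted p = 1.14e-05, and 0.562 with an estimated correlation). Epithelial genes were higher in 19 of 20 (median 0.21, Cldn4 0.38; adjusted p = 0.00187, and 0.562). Tcf3-repressed genes were higher in 10 of 10 (median 0.28, Tfcp2l1 0.80 ± 0.38; adjusted p = 0.0161, and 0.562) and pluripotency genes in 19 of 26 (median 0.19, Dppa5a 0.88 ± 0.33; adjusted p = 0.0187, and 0.666), and both calls were lost among genes above the floor on every array (0.470 and 0.218) and with the plan as written (0.170 and 0.167). Lower as sets were also the neural (median -0.22, Zic1 -0.74 ± 0.27, Tubb3 -0.69; adjusted p = 0.00491, and 0.43 with an estimated correlation), cell cycle (median -0.17, Mki67 -0.28; adjusted p = 0.00463, and 0.607), imprinted (median -0.092, Rian -0.45 ± 0.13; adjusted p = 0.000107, and 0.411) and endoderm genes (median -0.048; adjusted p = 0.0104, and 0.43). The p53 genes were higher in all 14 cases (median 0.079, Perp 0.17; adjusted p = 0.00853, and 0.43 with an estimated correlation). Wnt targets (median -0.012, adjusted p = 0.428), Tcf/Lef components (0.305), mesoderm (0.9), trophoblast (0.363), germline (0.305), macrophage (0.305), endothelial (0.305), muscle (0.732), glycolysis (0.307) and sex-linked genes (0.732) did not pass. Adjusted over the list alone, Tcf7l1 fell in the Tcf/Lef list and no other member of any list passed.

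Most of these list calls depended on single days. Without day 26 the pluripotency (adjusted p = 0.870), Tcf3-repressed (0.870), epithelial (0.684), neural (0.154) and p53 (0.154) calls were lost and the glycolysis list passed as lower (0.00523). Without day 22 the pluripotency (0.291), Tcf3-repressed (0.133), mesenchymal (0.542) and endoderm (0.253) calls were lost. Without day 19 the pluripotency (0.0599) and interferon (0.0599) calls were lost and the germline list passed as higher (0.0315). Without day 15 the neural (0.153) and p53 (0.0538) calls were lost and the cell cycle median turned to 0.054 (0.348), and without day 11 the cell cycle call was lost (0.0544). The median pluripotency difference of ko and wt was 0, -0.16, 0.12, 0.23 and 0.86 on the 5 days, and the mesenchymal one 0.021, 0.13, -0.058, -0.46 and -0.17. Exact sign-flip permutation tests of list means over days reached no p under 0.0625, the smallest possible, which the imprinted list met.

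The difference of the slopes asks whether ko cultures changed at another rate than wt cultures. Pluripotency genes had the more positive slope in ko in all 26 of 26 cases, with a median of 0.093 log2 per day and 0.18 ± 0.093 for Tdgf1 and 0.17 ± 0.041 for Tfcp2l1. Among the largest positive differences were those of Ctsj at 0.21 ± 0.064, Tpbpa at 0.17 ± 0.074, and the prolactin family members Prl7d1 at 0.19, Prl2a1 at 0.19 and Prl7b1 at 0.18. Among the most negative ones were -0.24 for the RNA-binding protein Elavl4, -0.24 for the neurofilament protein Ina, -0.21 for Stmn3 and -0.20 for the migration gene Dcx. None of these genes passed, as limma called 0 of 13428 genes, with 208 at an unadjusted p under 0.05 (56 higher, 152 lower), in a fit that has no term for the days shared by both genotypes. With day as a block, which leaves 3 residual degrees of freedom, the slope differences were the same and limma also called 0, with 1101 genes at that level and a smallest adjusted p of 0.429. The plan as written gave 0 calls with 259 at that level. The 208 and the 259 are under a share of 0.05 of the genes tested, and the 1101 are above it. Others named were Ooep (0.17), Ceacam9 (0.16), Trh (0.15), Tmem130 (-0.25), Rtn1 (-0.22), Nnat (-0.20), Nsg2 (-0.20), Fabp7 (-0.20) and Cracd (-0.19).

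Arrays of day 26 stood out for these genes. There, Dcx, Elavl4 and Ina reached 9.72, 10.09 and 11.24 in wt, while in ko Dcx and Elavl4 were at the floor and Ina at 6.67. Prl7d1 and Prl7b1 were at 9.22 and 8.89 on ko day 26 and at the floor on all other arrays. Tpbpa went from 5.92 on day 22 to 8.72 on day 26 in ko, and Ctsj from 6.88 to 8.999. Dppa5a reached 10.24 in wt and 12.47 in ko on day 26, and Nanog 9.23 and 9.79.

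By camera the pluripotency (adjusted p = 3.5e-17; 0.00209 with an estimated correlation), Tcf3-repressed (median 0.094, 6.94e-11; 0.00497), trophoblast (median 0.049, 0.000754; 0.0129) and germline (median 0.072, 0.00223; 0.00497) lists gained more in ko, and these calls held with an estimated correlation. The Tcf3-repressed list shares most of its genes with the pluripotency list, so the calls of these lists are not independent. The germline list had 4 tested genes, and its call was lost with the plan as written (median 0, 0.162). By fry no list passed (pluripotency adjusted p = 0.460, smallest 0.242). With day as a block the 4 lists passed by camera at the preset correlation, but not with an estimated one (0.0976, and 0.227 for the germline list) or by fry (pluripotency 0.445, smallest 0.293), the muscle call was lost (0.0604), and the imprinted call held with an estimated correlation (0.00424). Epithelial (0.054, adjusted p = 6.16e-06; adjusted p = 0.261 with an estimated correlation), cell cycle (0.051, 9.63e-06; 0.309), glycolysis (0.032, 0.00051; 0.261), endothelial (0.033, 0.0379; 0.0761) and muscle lists (0.024, 0.0377; 0.261) also had positive medians, with calls that did not hold with it. Negative medians, with calls that likewise did not hold, were those of the mesenchymal (-0.025, adjusted p = 0.000406; adjusted p = 0.473 with an estimated correlation), neural (-0.028, 0.0171; 0.209) and imprinted lists (-0.026, 0.0053; 0.19). Wnt targets (0.929), Tcf/Lef components (0.798), mesoderm (0.433), endoderm (0.195), p53 (0.433), interferon (0.913), macrophage (0.913) and sex-linked lists (0.0704) did not pass. Adjusted over the list alone 1 Tcf3-repressed and 1 germline gene passed, both higher. Without day 26 the pluripotency median was 0.049, and the Tcf3-repressed (0.0597), trophoblast (0.703), germline (0.522), epithelial (0.522), endothelial (0.522), muscle (0.343), imprinted (0.379), glycolysis (0.132) and neural (0.950) lists did not pass and the endoderm list did, as lower (0.0311). Without day 11 the pluripotency median was 0.16, the neural and endothelial calls were lost (0.111 each), and the interferon (2.7e-05) and sex-linked (0.00603) lists passed as higher, the latter also without day 22 (0.00786).

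OSK ko iPSC clones against the OSK wt clone ask how established iPSC without Tcf3 differ from a wt one. With 1 wt clone, a difference between clones cannot be told from an effect of Tcf3 loss. The SD of log2 differences, over probe sets above the floor on both arrays, was 0.302 and 0.309 between the wt and the ko clones. It was 0.152 between the OSK ko clones, but 0.376 between the OCK ko clones, which share genotype and factor set. Csrnp3 rose by 2.70 ± 0.15 (SE, 2 ko and 1 wt array; adjusted p = 0.00989), and the naive pluripotency factor Klf2 by 1.13 ± 0.15. The Wnt target and homeobox gene Cdx1 rose from the floor in the wt clone and was at least 6.12-fold higher in ko. Car4, a carbonic anhydrase, fell (-3.07 ± 0.29), as did the muscle LIM protein Fhl1 (-2.16 ± 0.10, adjusted p = 0.00799) and the neural progenitor factor Sox1 (-1.77 ± 0.21). Pou5f1 (0.15 ± 0.20), Sox2 (0.10 ± 0.15) and Nanog (0.011 ± 0.21), chosen after their values were seen, did not pass. Of 12670 genes tested 87 passed, 38 higher and 49 lower in ko, of which 34 and 41 by at least 2-fold, and 1623 had an unadjusted p under 0.05.

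Other genes that rose were Dnah8 (2.43), a dynein chain of cilia and sperm tails, the peptidase Dpp4 (2.24), the proteoglycan Srgn (2.19), the histidine lyase Hal (2.03), Kyat3 (1.70), Pla1a (1.67), Ephx2 (1.55) and the alkaline phosphatase Alpl (1.51). Others that fell were the G protein subunit Gna14 (-2.35), Kbtbd11 (-2.19), Krt17 (-1.93) and the neuronal Map2 (-1.86); Gna14, Krt17 and Map2 were above the floor in 1 of the 2 ko clones. At the floor in both ko clones were Ptn (at least 3.55-fold lower), Fndc3c1 (at least 3.49-fold) and the fibrillin Fbn2 (at least 3.47-fold). Of the 87 genes 12 were on the X chromosome and 2 on chromosome 12, all lower in ko. The median difference over 342 X-linked genes was -0.21 and over 390 chromosome 12 genes -0.22, while the other autosomes had medians from 0.0014 to 0.048.

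Of the lists below, camera called 8 and fry none (smallest adjusted p = 0.0628). Of 12 Tcf3-repressed genes 2 rose (Cdx1 and Klf2), and adjusted over the list alone 5 rose and 2 fell; the median was 0.41 and the list lay higher as a set (adjusted p = 0.00449; 0.00347 with an estimated correlation). Of 12 Wnt targets Cdx1 rose, and adjusted over the list alone 4 did; the set lay higher (median 0.15, adjusted p = 0.000481; 0.0192). Axin2, chosen after its values were seen, was among these 4 (1.13 ± 0.16), Tnfrsf19, with the wt clone at the floor, was at least 4.46-fold higher, and Lef1 was at 0.75; these 2 did not pass over all genes, nor did Axin2. Lower as sets were the neural genes (Map2 and Sox1 fell; median -0.32, adjusted p = 1.57e-06; 6.79e-05), the epithelial genes (Krt18 fell by 1.16; median -0.23, adjusted p = 0.000441; 0.000134), the muscle genes (median -0.13, adjusted p = 5.97e-06; 4.26e-06) and the imprinted genes (median -0.64, adjusted p = 0.000165; 6.79e-05). In the muscle list the actins Acta1 and Actc1 fell to the floor in both ko clones, by at least 2.81-fold and 2.42-fold. Of 14 imprinted genes Grb10 rose (1.47 ± 0.15) and 3 fell, 5 adjusted over the list alone, with Peg3 at -1.45 and, chosen after their values were seen, Mest (-1.07) and Peg10, which fell to the floor. Mesenchymal genes were lower in 24 of 28 cases (median -0.66, Postn, chosen after its values were seen, fell to the floor, 3 fell adjusted over the list alone, Tagln -2.35 ± 0.65 and Col3a1 -1.96 not passing; adjusted p = 5.02e-05, and adjusted p = 0.301 with an estimated correlation). Endoderm genes were higher in 14 of 15 (median 0.23, Cubn at least 3.48-fold higher from a wt at the floor, not passing; adjusted p = 0.0161, and adjusted p = 0.301 with an estimated correlation).

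In the pluripotency list Klf2 was the 1 of 27 that passed, and 4 rose and 2 fell adjusted over the list alone (Tbx3 1.07, Nr0b1 -0.77, Tcl1 -0.72; list adjusted p = 0.146). In the germline list 5 rose and 2 fell adjusted over the list alone (Dazl 1.46, Stk31 1.01, Rhox9 -2.26; adjusted p = 0.0543). The Tcf/Lef (0.146), mesoderm (0.923), trophoblast (0.744), two-cell-like (0.177), cell cycle (0.923), p53 (0.713), interferon (0.713), macrophage (0.166), endothelial (0.713) and glycolysis (0.936) lists did not pass, and without OSK ko clone 2 the two-cell-like list did (0.0260). Without chromosomes X, Y and 12 the pluripotency (median 0.13, adjusted p = 0.0054) and germline lists (median 0.54, 0.000321) passed as higher, as they did in the 3 OSK arrays alone (0.0255 and 0.00387). Leaving out OSK ko clone 1 or clone 2 left 0 calls by limma, with 913 and 879 genes at an unadjusted p under 0.05, and the fit of 5 iPSC arrays 0 with 1300; the fit of the 3 OSK arrays called 983, the plain prior 52, genes above the floor on every array 28, and the plan as written 123, 27 of them shared. Among genes above the floor on every array the Tcf3-repressed (0.512), Wnt (0.470), endoderm (0.287), neural (0.803) and muscle (0.917) calls were lost, and with the plan as written those of 6 lists (0.994 each), the muscle and imprinted calls excepted.

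**Figure D3:**
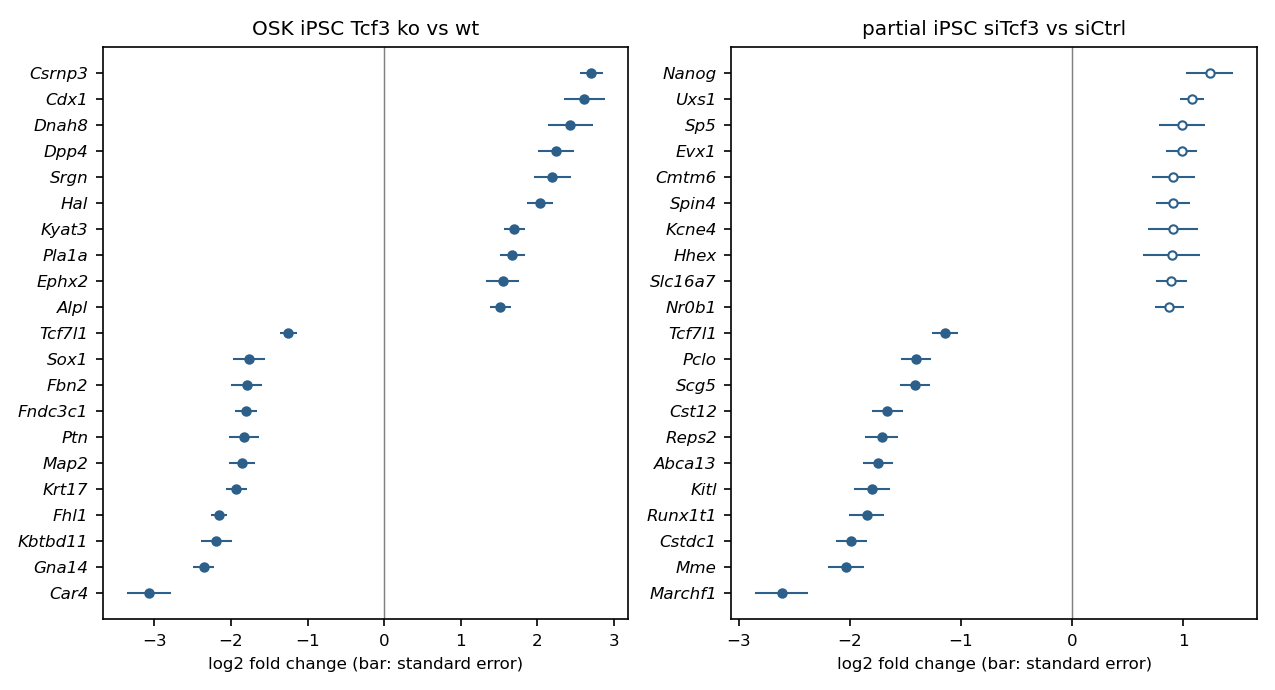
Log2 differences with standard errors of the largest named changes in OSK ko against wt iPSC clones and in Tcf3 siRNA against control siRNA; filled points passed limma's test over all genes and open points did not. Every change shown in the clones passed, from -3.07 for Car4 to 2.70 for Csrnp3, and after siRNA every fall shown passed and no rise did; where a group lay at the floor the point is a bound.

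OCK against OSK ko clones ask how the factor set is reflected in iPSC that both lack Tcf3; there was no OCK wt clone, and each factor set had 2 clones. The neurogenic factor Neurod1 fell to the floor in OCK clones (at least 9.90-fold lower), and Srgn fell by 3.05 on the log2 scale. The non-coding RNAs Meg3 (-2.31 ± 0.37), Mirg (-1.99) and Rian (-1.95), which are transcribed from 1 imprinted locus on chromosome 12, fell together. S100a13 rose by 2.73 ± 0.53, the lipid synthesis enzyme Gpat3 by 2.67 ± 0.31 and the pluripotency-associated Tcl1 by 1.63 ± 0.11. Genes on the X chromosome rose widely: 210 of the 1377 genes that passed lay on it, all of them higher in OCK, and 315 of 342 X-linked genes above the floor on every array were higher, with a median of 0.59 against -0.087 to 0.013 for the autosomes. Of 12905 genes tested 629 rose and 748 fell, 194 and 121 by at least 2-fold, and Tcf7l1 did not pass (0.071 ± 0.093, adjusted p = 0.672). The fit pools the spread of unlike pairs of arrays. The SD of log2 differences was 0.376 between the OCK clones, 0.152 between the OSK ko clones and 0.221 between the Tcf3 siRNAs. Between an OCK and an OSK ko clone it was 0.386 to 0.457, so the OCK clones differed from each other nearly as much.

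Other large rises were those of Serpinb1a (2.64), the X-linked Dcaf12l1 (2.63), Klhl13 (2.20) and Rhox9 (2.19), Apobec2 (2.44), Calcoco2 (2.42), the two-cell-stage gene Tcstv1 (2.22), and the sialyltransferase St8sia1 (at least 5.11-fold, OSK clones at the floor). Other large falls were those of Crmp1 (-2.50), Enpp3 (-2.35), Naprt (-2.29), Slc7a7 (-2.20) and Mapk4 (-2.003).

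Of 27 pluripotency genes 4 rose and 0 fell, 7 and 1 adjusted over the list alone, with Prdm14 at 1.64, Tcl1 at 1.63 and Tbx3 at 1.21 and, chosen after its values were seen, Fbxo15 at 0.99, and Lin28a (-1.94) not passing (list adjusted p = 0.00788; adjusted p = 0.0634 with an estimated correlation). Of 12 Tcf3-repressed genes Tcl1 and Tbx3 rose and Cdx1 fell (-1.03), with 6 higher and 1 lower adjusted over the list alone (median 0.31, adjusted p = 0.00589; 0.00294 with an estimated correlation). Of 13 imprinted genes 6 fell, Meg3, Mirg and Rian among them, and Ndn rose (1.14), with the same counts adjusted over the list alone (median -0.37, adjusted p = 0.00589; 0.00279). Of 15 endoderm genes 5 fell, 6 adjusted over the list alone, with Cubn at the floor in OCK and at least 3.48-fold lower (median -0.49, adjusted p = 0.0167; adjusted p = 0.451 with an estimated correlation). By fry none of these lists passed (smallest adjusted p = 0.0639). Without genes of chromosomes X, Y and 12, 986 genes passed (352 higher, 634 lower) and the 4 lists fell short of the threshold, with medians of 0.21 (pluripotency), -0.48 (endoderm) and -0.16 (imprinted; adjusted p = 0.0645 each) and 0.40 (Tcf3-repressed; 0.0766), so that the imprinted median alone came much nearer to 0. With the plan as written they fell short too (0.952, and 0.372 for the imprinted list), and among genes above the floor on every array the pluripotency (0.322) and Tcf3-repressed (0.102) lists did.

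In the other lists single members passed without the list. Among Wnt targets Apcdd1 rose (1.56) and 3 of 12 fell, Lef1 (-1.53), Cdx1 and, chosen after its values were seen, Axin2 (-0.66) (list adjusted p = 0.639), and Lef1 was 1 of 2 falls in the Tcf/Lef list (0.287). Of 13 glycolysis genes 3 fell, 7 adjusted over the list alone, with Pdk1 at -1.87, Aldoc at -1.22 and, chosen after its values were seen, Pfkp at -0.59 (0.107). In the germline list 2 rose, 5 adjusted over the list alone, with the X-linked Rhox9 and Rhox5 (2.00) (0.126), and in the two-cell-like list Tcstv1 (0.117). Dsp rose (1.32) and Spint2 fell (-0.49) in the epithelial list (0.432), Perp rose (0.85) and Sesn2 fell (-0.44) in the p53 list (0.328), Map2 rose (2.07) in the neural list (0.365) and Oas1a (1.64) in the interferon list (0.779). Egfl7 fell (-0.49) in the endothelial list (0.873) and Tnnt1 (-1.20) in the muscle list (0.195), and no member passed in the mesoderm (0.873), trophoblast (0.422), cell cycle (0.873) and macrophage lists (0.873). The mesenchymal list (median 0.17, adjusted p = 0.779) turned with the clone: its median was 0.55 without OCK ko clone 1 (adjusted p = 5.07e-15) and -0.41 without clone 2 (0.00658). The number of calls was 8 without OSK ko clone 1, 18 without clone 2, 2958 without OCK ko clone 1, 3614 without clone 2, 294 in the fit of 5 iPSC arrays (175 higher, 119 lower), 528 with the plan as written (237 higher, 291 lower; 393 shared), 142 with the clone number as a block (95 higher, 47 lower; 140 shared) and 285 with crossed clone numbers (169 higher, 116 lower; 282 shared). The balance of rises and falls thus changed with the setting. Leaving out an OCK clone takes the wide spread of the OCK pair out of the fit. Leaving out an OSK ko clone takes out the narrow spread of the OSK ko pair. The number of calls therefore depends on this pooling. Without OCK ko clone 2 the Tcf3-repressed (0.0698) and endoderm (0.116) calls were lost and the germline (0.00237) and two-cell-like (0.00068) lists passed, as they did without OSK ko clone 1 (0.0131 and 0.0177), and without OCK ko clone 1 the glycolysis list did (0.000192).

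**Figure D4:**
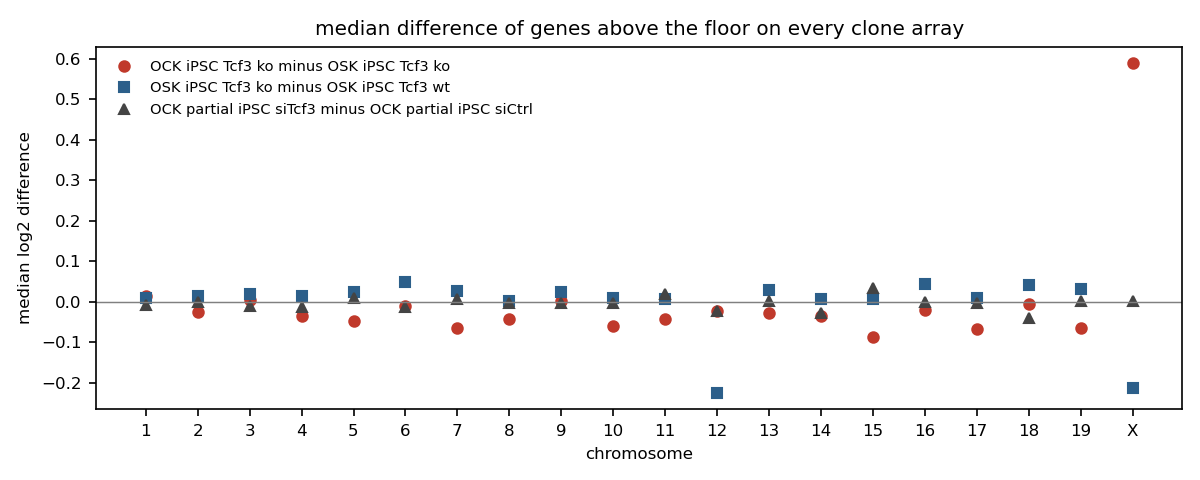
Median log2 difference of genes above the floor on every array, by chromosome, for OCK ko minus OSK ko clones, OSK ko minus wt clones and Tcf3 siRNA minus control siRNA. The X chromosome stands at 0.59 in the first and at -0.21 in the second difference, and chromosome 12 at -0.22 in the second.

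The siRNA arrays ask what an acute loss of Tcf3 does in a partial iPSC clone by day 2. The ubiquitin ligase gene Marchf1 fell by 2.61 on the log2 scale (SE 0.24, 2 siTcf3 and 1 siCtrl array; adjusted p = 0.0447), the membrane peptidase Mme by 2.04, the transcriptional corepressor Runx1t1 by 1.85 and the Kit ligand gene Kitl by 1.80. Other falls were those of Abca13 (-1.75), the X-linked Reps2 (-1.71), and Cst12 (-1.66) and Scg5 (-1.41), both above the floor with 1 of the 2 siRNAs. Cstdc1 and Pclo fell to the floor with both, by at least 3.96-fold and 2.65-fold. Nanog (1.24 ± 0.21, adjusted p = 0.114), Nr0b1 (0.87 ± 0.13, adjusted p = 0.0922) and Uxs1 (1.08 ± 0.11, adjusted p = 0.0537) were higher with both siRNAs and did not pass. Of 12636 genes 14 passed, all lower and at least 2-fold, 5 of them with a floored array, and 1602 had an unadjusted p under 0.05, 545 higher and 1057 lower. Other high values that did not pass were those of Sp5 (0.99), Evx1 (at least 1.98-fold, control at the floor), Cmtm6 (0.91), Spin4 (0.91), Kcne4 (0.90), Hhex (at least 1.86-fold, control at the floor) and Slc16a7 (0.89).

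Over all genes Tcf7l1 was the only list member that passed, so the lists rest on shifts of whole sets, which camera called for 9 lists and fry for the Tcf3-repressed (adjusted p = 0.038) and sex-linked (0.00449) lists alone. Tcf3-repressed genes lay higher (median 0.15, 7 of 9 positive, 3 adjusted over the list alone, Nanog, Nr0b1 and Sp5 highest in value; adjusted p = 0.000176; 0.00085 with an estimated correlation), as did all 6 mesoderm genes (median 0.36, Mesp1 0.67, 2 adjusted over the list alone; adjusted p = 6.93e-05; 0.00104). Cell cycle genes were higher in 17 of 18 (median 0.28, Aurka 0.54, Ccna2 0.46; adjusted p = 9.44e-07; 0.0232). All 14 p53 and senescence genes were lower (median -0.38, Btg2 -0.77, Cdkn2a -0.76, 2 adjusted over the list alone; adjusted p = 0.000176; 0.0379). Lower as sets were also the trophoblast (median -0.25, Elf5 at the floor with both siRNAs and at least 2.12-fold lower; adjusted p = 0.0131; 0.0202), imprinted (median -0.34; adjusted p = 0.0483; 0.0433) and sex-linked genes (median -0.31, Xist at the floor with both siRNAs and at least 1.86-fold lower; adjusted p = 0.00436; 0.00611). The mesenchymal (median -0.39, 25 of 28 negative; adjusted p = 0.00563, and adjusted p = 0.525 with an estimated correlation) and interferon lists (median -0.30; adjusted p = 0.0131, and adjusted p = 0.292 with an estimated correlation) were lower at the preset correlation alone. The pluripotency (0.0552), epithelial (0.0552, Krt8 -1.26), Tcf/Lef (0.0511), endoderm (0.0919), Wnt target (0.499), neural (0.583), germline (0.918), macrophage (0.711), endothelial (0.509), muscle (0.499) and glycolysis (0.499) lists did not pass at the preset correlation, and the epithelial (0.0459) and Tcf/Lef (0.0453) lists passed as lower with an estimated one. By camera the sex-linked call was lost with the mean of probe sets, and the trophoblast call among genes above the floor on every array. Sex-linked, mesenchymal and p53 genes lay lower together while cell cycle genes lay higher, and Y-linked genes and Xist both gave signal with control siRNA. Changed levels within cells and a changed mix of cells cannot be told apart by these arrays, and neither was tested. Limma called 1 gene without siRNA A, 0 without siRNA B and 0 among genes above the floor on every array, but 66 with the plain prior, 412 in a fit of the 3 siRNA arrays, 252 with the plan as written (9 shared), and 8 each with quantile normalization, median centring or the mean of probe sets. Without siRNA A the imprinted (0.178), mesenchymal (0.0780) and interferon (0.456) calls were lost and the pluripotency list passed (0.000322), without B the imprinted call was lost (0.0662) and the Tcf/Lef list passed (0.0320), and with the plan as written the Tcf3-repressed, mesenchymal, mesoderm, cell cycle, p53 and imprinted calls were lost (0.989 each).

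The 3 comparisons of Tcf3 loss share no array, so genes of one were tested in another, although the OSK and siRNA comparisons take their spread from 1 fit. Tcf7l1 was the 1 gene called in both the OSK clones and after siRNA. Of the 68 OSK calls tested after siRNA 49 had the same sign there, and 4 of the 6 siRNA calls tested in OSK clones. At an unadjusted p under 0.05 in both, 197 genes moved the same way and 100 in opposite ways; since both comparisons take a gene's spread from 1 fit, genes of low spread reach that level in both whatever their agreement, and no expected number is given. The log2 changes correlated across 11903 genes with r = 0.12. Limma's test of the difference between both changes called 0 of 13403 genes (smallest adjusted p = 0.0845, 1662 at an unadjusted p under 0.05). The 100 genes with the smallest p among those higher in ko cultures, none of which passed there, had a median of -0.018 in OSK ko clones (camera adjusted p = 0.931). After siRNA their median was -0.12 (camera adjusted p = 0.00634, p = 0.0679 with an estimated correlation, fry adjusted p = 0.135). That shift is opposite to the cultures, as only 30 of 92 tested genes kept their sign. The 100 lower in ko cultures had medians of -0.10 in OSK ko clones and -0.051 after siRNA (camera adjusted p = 0.0753 each).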

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

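The tests of X-linked genes, of scaling and of Tcf3 loss for chromosome 12, and of fibroblast-like cells were chosen after the result was seen. The other tests were written before their values were known. The readings of the test of a single deciding day and of the counts of calls in splits were made more cautious after their values were seen. Probe sets to which the array annotation gives no gene entered no comparison, and some of them carried signal. In the change per day 402 of 3124 such probe sets passed limma's test, 213 higher and 189 lower. Between OCK and OSK ko clones 73 of 2593 passed, 36 higher and 37 lower. In the other 4 comparisons 0 of them passed.

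X-linked genes were higher in OCK than in OSK ko clones, with a median of 0.59 over 342 genes. A scaling between arrays that depends on signal level is argued against, since the X median lay 0.628 above autosomal genes of like level. After quantile normalization the X median lay 0.617 above that of the autosomes. That step could change little, as RMA had already normalized the arrays and it treats genes of like level alike. A single odd clone is argued against too, since the smallest X median of the 4 pairs of clones was 0.573. A candidate explanation is a higher output of the whole X chromosome in the OCK clones. That 92.1% of its genes were higher restates the pattern and does not test this explanation. The OSK wt clone lay between (-0.21 for OSK ko minus wt and 0.33 for OCK ko minus OSK wt). The factor set, the cell line of each clone and the number of active X chromosomes cannot be separated by these arrays and stay open, and DNA copy number was not analysed here.

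Chromosome 12 genes were lower in OSK ko than in OSK wt clones, with a median of -0.22 over 390 genes, 324 of them lower. A scaling that depends on signal level is argued against, since the chromosome 12 median was -0.25 relative to genes of like level on the other autosomes. After quantile normalization, which could change little here too, it was -0.25 relative to the other autosomes. A general effect of Tcf3 loss is argued against by a median of -0.0236 after Tcf3 siRNA and 0.018 in ko cultures. A candidate explanation is a higher output of chromosome 12 along its length in the lone wt clone: 4 equal parts of its genes in map order had medians of -0.26, -0.22, -0.20 and -0.23, the weakest being -0.196, and OCK ko clones were also lower than the wt clone (-0.26). An effect of Tcf3 loss that arises only in established clones stays open, as only 1 wt clone was measured.

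The slope differences of pluripotency genes between ko and wt cultures had a median of 0.093 per day, and camera placed the list above other genes. None of its 26 genes passed, over all genes or adjusted over the list alone, and by fry the list did not pass (adjusted p = 0.460, and 0.445 with day as a block), so the pattern is weighed here as a shift that is not established. Fewer fibroblast-like cells in late ko cultures stay open: the mesenchymal slope difference was negative in 28 of 31 genes (median -0.025), which goes with it, while the mesenchymal ko minus wt difference was smaller on day 26 (-0.172) than on day 22 (-0.46), on 1 array per genotype and with markers of high level that would hide a small change of share. Whether 1 day carries the pattern stays open: the lowest median with a day left out was 0.0487, without day 26. By the rule as first written this value argued against a single deciding day. It lay above the limit of that rule by less than the spread of these medians. The margin for that spread was added after the value was seen. Chance could not be excluded, since 9 of 100 splits of the 10 culture arrays gave a median as large, with 0.134 as the highest other. The 8 others as large keep both arrays of at least 1 day together, so their slopes rest in part on different days. Among the 14 splits that set 1 array of each day against the other, as the genotypes do, the real value was the largest (highest other 0.091), and these are too few for a share under 0.05.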

How the results depend on the processing

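The alternatives that change the prior or the set of genes for the floor, the fits of days 19, 22 and 26 alone and without chromosomes X, Y and 12, the crossed clone numbers and the 2 fits for shared days were chosen after the data were examined; the others were planned. Of 6985 values of named genes under the alternatives, 6271 kept their direction and side of the threshold, 474 fell short of it, 128 newly passed and 112 without a call moved. Of 1661 list values 1436 kept theirs, 86 fell short, 36 newly passed, 93 moved and 10 reversed. Of the counts of called genes 29 compare 0 calls with 0 and show nothing about stability; of the rest 27 stayed within 1.5 times and 28 did not. The change per day fell from 4921 calls to 424 with a line through the 5 day means (28 of its named genes fell short), and the slope difference had 0 with day as a block.

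With a single day, clone or siRNA left out, the number of genes called ranged from 0 to 1 (culture ko against wt), 0 to 5151 (change per day), 0 to 0 (OSK ko against wt), 8 to 3614 (OCK against OSK) and 0 to 1 (Tcf3 siRNA). With the plan as written it was 3171 (change per day), 528 (OCK against OSK) and 252 (siRNA), where genes with no residual spread lower the prior. For OSK ko against wt the plain prior gave 52, genes above the floor on every array 28, the 3 OSK arrays alone 983 and the 5 iPSC arrays 0. For OCK against OSK the 5 iPSC arrays gave 294, the clone number as a replicate block 142 and crossed numbers as a block 285. The labels do not say whether equal numbers pair the clones. The differences between clones 1 and 2 of the 2 factor sets correlated at -0.129 across 11603 genes, which shows no sign of pairing. It cannot exclude pairing, as it is a single correlation and the OSK ko clones differ little from each other. For the siRNA the mean of probe sets, quantile normalization and median centring gave 8 each, the plain prior 66, genes above the floor 0 and the 3 siRNA arrays alone 412. The balance of directions moved too: in OSK ko against wt 38 higher and 49 lower became 34 and 89 with the plan as written and 37 and 34 without chromosomes X, Y and 12, and after siRNA 0 and 14 became 52 and 200 with the plan. Apart from fits with fewer arrays, the cause was not tested.

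List medians that reversed were those of the cell cycle in culture ko against wt (-0.17; from -0.32 to 0.054 with a day left out, 0.17 in days 19, 22 and 26 alone), of glycolysis there (0.16 in those days), of Tcf3-repressed genes in the change per day (-0.011 among genes above the floor), and of Wnt targets (-0.068) and muscle genes (0.025) in OSK ko against wt among genes above the floor, a set without the floored genes that carried them. With a day left out the slope difference ranged from -0.053 to 0.0054 for neural, -0.0032 to 0.12 for germline and -0.021 to 0.060 for interferon genes. The mesenchymal median of OCK against OSK ranged from -0.41 to 0.55 with a clone left out. Calls of the imprinted list were also lost in the change per day with the mean of probe sets (adjusted p = 0.0987), quantile normalization (0.0676) and genes above the floor (0.0848), and that of the macrophage list with the last (0.287). After siRNA the sex-linked (0.112) and imprinted (0.105) calls were lost with the mean of probe sets, the imprinted call also with the plain prior (0.102) and a minimum of log2 6 (0.0557), and the trophoblast (0.957) and interferon (0.676) calls among genes above the floor. In culture ko against wt the pluripotency call was lost with the mean of probe sets (0.0555), median centring (0.0790), the plan as written (0.167) and genes above the floor (median 0.075, 0.218), the Tcf3-repressed call with the last 2 (0.170, and median 0.11, 0.470), the endoderm call with the plan (0.0641), and the neural (0.0511) and p53 (0.197) calls in days 19, 22 and 26 alone. In the slope difference the germline call was lost with the plan (median 0, 0.162), the neural call with the mean of probe sets (0.0545), the endothelial call with that (0.109), the plan (0.0968) and genes above the floor (0.166), and the muscle call with these 3 (0.0576, 0.283 and 0.357) and the plain prior (0.0786). For OCK against OSK the pluripotency (median 0.17, 0.322) and Tcf3-repressed (median 0.40, 0.102) calls were lost among genes above the floor. The glycolysis list of OCK against OSK newly passed with the mean of probe sets (0.0384), a variance trend (0.0302) and genes above the floor (0.0493), and with the clone number as a block the germline (0.0175) and two-cell-like (4.45e-06) lists did. In OSK ko against wt the germline (0.0353) and Tcf/Lef (0.0482) lists newly passed with the mean of probe sets. After siRNA the endoderm (0.0399) list newly passed with quantile normalization, the epithelial and endoderm lists with median centring (0.043 each) and in the 3 siRNA arrays (0.0029 each), and the pluripotency (0.0268), Tcf/Lef (0.0268) and epithelial (0.0262) lists with a variance trend. The floor limits every fold that involves a group at it, and 44.9% to 46.6% of the values on an array lie there.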

Other observations

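The adipocyte test and its gene list were chosen only after Adipoq, Cd36 and G0s2 had been seen to be lower in ko cultures. The counts of splits were planned, but their reading as undecided was set after the values were seen. Sex-linked genes set the clones apart from the other samples. The Y-linked genes Eif2s3y, Kdm5d and Uty were at the floor in all 5 iPSC clones, and lay between 7.4 and 9.8 in all cultures and in the partial clone. Xist, the RNA that silences an X chromosome, was also at the floor in the 5 clones, between 5.86 and 7.59 in the cultures, at 6.54 with control siRNA and at the floor with both Tcf3 siRNAs.

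Genes of fat cells lay lower in ko than in wt cultures over the 5 days together, although no single gene passed. A list of 21 adipocyte genes without Adipoq, Cd36 and G0s2, none of which is in another list, had 17 tested members, all lower in ko, with a median of -0.304 (camera p = 1.24e-25; p = 3.3e-07 with an estimated correlation; fry p = 0.0133; sign-flip over days p = 0.0625, the smallest it can give). Other markers moved in this comparison too, with mesenchymal genes lower in 28 of 31 cases and epithelial genes higher in 19 of 20. The camera calls of these and of all other fixed lists failed by fry (smallest adjusted p = 0.749). The smallest unadjusted fry p of a fixed list was 0.101 (Tcf/Lef components). The adipocyte p-values are not adjusted and come from a list chosen after these data were seen, so they are not alike. The median was -0.0062 on day 11, and -0.35, -0.32, -0.39 and -0.19 on days 15, 19, 22 and 26, so the list hardly differed on day 11. The fatty acid binding protein Fabp4 (-0.45), the lipoprotein lipase Lpl (-0.35), Cebpa (-0.33) and Scd1 (-0.25) were lower on all 5 days, and the lipid droplet genes Cidec (-0.90) and Plin4 (-0.89) on 4. The list's abundant members were high in both genotypes, with means of 13.45 in wt and 13.10 in ko for Lpl and 13.04 and 12.59 for Fabp4. Adipoq was at 7.005, 11.91, 10.99, 11.01 and 10.46 in wt and at 6.05, 11.17, 9.96, 9.72 and 9.40 in ko on the 5 days. Less RNA of adipocyte-like cells in ko cultures and a lower level within each cell cannot be told apart, as both give a negative median. The labels do not say whether the days of a genotype came from 1 culture. A lasting difference between the wt and ko cultures that is unrelated to Tcf3 would give the same signs and cannot be told apart either. Of 100 splits of the 10 arrays 17 gave a median as large (highest other 0.391), the real one included, but 13 of them part the arrays of 1 day only. With the day as a block such a split returns the real ko minus wt difference of that day, so this count does not bear on chance. The 14 splits that set 1 array of each day against the other, with the real value as the largest (highest other 0.204), are too few for a share under 0.05.

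The counts of called genes in the cultures were compared with those of other splits. With 0 genes called in ko against wt and in the slope difference, each of the 100 splits drawn from 126 (100 of 100) must call as many, so this comparison says nothing about chance. The highest other counts were 458 and 2141. The 458 came from 4 splits that part the arrays of day 26 only, which with the day as a block test the ko minus wt difference of that day. The 2141 came from a split that parts day 15 only, so that the slopes compared rest on different days; the cause was not tested. The 14 splits that part every day called 0 genes in both tests.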
